A study of Danio rerio with 8 samples.

How the data were processed

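The 8 arrays measured total RNA of whole embryos, labelled with biotin and hybridized to the Affymetrix zebrafish genome array. The deposited values are a microarray intensity for each probe set on a linear scale. MAS5 is the only processing tool named per the submitters' processing notes, and its version, background setting and scaling target are not given in the sources used here. The labels name 2 biological repeats of each group at 24 and 30 hpf and give no batch or scan information. Dates and batches are not given in the sources used here. All 8 columns of the table were matched to a sample by its label, and 0 were left unmapped.

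The deposited arrays differed in scale. The mean of the deposited intensity after trimming 2% at each end was 500.1 on replicate 1 of the 30 hpf wild type and 58.9 to 80.8 on the other arrays. On that array the hybridization controls stood at 7.05 times, the poly-A controls at 6.99 times and all probe sets at 7.47 times the median of the others. The design fixed beforehand used log2 values as deposited, which assumed 1 common scale. That setting was kept as an alternative, and quantile normalization, which had been listed as an alternative, took its place: each array was scaled to a trimmed mean of 500, a pseudocount of 1 was added, log2 was taken and the arrays were quantile-normalized with limma 3.58.1 in R 4.3.3. This change was made after the values were seen. A fold change is on the scale of log2(scaled signal + 1), which understates the change of dim probe sets.

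Of 15617 probe sets, 115 controls were left out. Of the remaining 15502, 10795 carry 1 gene symbol in the platform annotation of 2016, 135 carry several and 4572 carry none; genes were named only from those with 1 symbol. Symbols were checked through Entrez identifiers, which matched for 10711 probe sets, and 8793 different genes are named. Probe sets at or above the 40th percentile of mean log2 signal were tested, 9301 in all. For gene lists and correlations the probe set with the highest mean signal stood for each gene, which gave 6271 genes. No reference genome was used here, so no coordinates are given.

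A limma fit with 1 mean for each of the 4 groups shared 1 estimate of the spread (4 residual degrees of freedom, prior degrees of freedom 8.31, prior variance following signal). Contrasts gave mutant minus wild type at each age and in the mean of both ages, the difference of these effects between ages, and 30 minus 24 hpf in each genotype and in their mean. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05. The errors after ± are limma's standard errors, with n = 2 arrays per group.

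Before the data were examined, 42 gene lists were written from pathways, cell types and complexes relevant to a zebrafish embryo, and 40 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists. The same test was run with a correlation estimated from the arrays, where camera also uses only the 4 residual degrees of freedom. So p can rise even where the estimated correlation is low. For glycolysis and hypoxia genes with age that correlation was -0.0122, and camera's p went from 1.015e-09 to 0.0021. A list call lost this way is therefore not by itself a sign that the members vary together. The list tests on the difference between ages and on age were added after the data had been seen. Named genes follow a rule fixed before the data were examined. In each genotype comparison these are the 10 largest rises and the 10 largest falls among 1-symbol probe sets past the threshold with every mutant array on one side of every wild-type array within each age compared. For age and for the difference between ages the numbers are 6 and 6. Where fewer than 5 pass in a direction, the 5 with the smallest p are given as values only. For each list, up to 4 members with the smallest p in the comparison described can be named. Probe sets annotated to stac, stac2 or stac3 are always given, of which there were 0. A probe set without a symbol is only counted, apart from at most 2 that rose and 2 that fell most. Where a gene named by this rule has several probe sets, the one with the smallest p is named, and disagreements are stated. As a list member, a gene is given by the probe set with the highest mean signal. Other probe sets of genes named only as list members were not compared.

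The code was tested on simulated arrays with the real means and array scales, run on 9301 probe sets. Noise was drawn independently with limma's moderated spreads, which already follow the trend with signal. The shares below may therefore not hold for the real arrays. In the simulated 30 hpf comparison, 44.8% of genes changed by 0.5 on the log2 scale, 82.1% of those changed by 1 and 95.5% of those changed by 2 were called in the right direction. Of the calls, 5% were of genes that had not been changed, and the simulated 24 hpf comparison, with nothing changed, gave 0 calls. A simulated list of 40 genes shifted by 0.3 was found and 0 of 20 unshifted lists were; the simulated genes varied independently, so this does not test lists whose members vary together.

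The alternatives were a pseudocount of 32, median centring, scaling without quantile normalization, values as deposited, no filter, a filter at the 60th percentile, no trend in the prior variance, a replicate block, leaving out each array in turn, fits on only the 4 arrays compared, 1 probe set per gene, an adjusted p below 0.1 and an estimated correlation for lists. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3.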

Results

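Whole zebrafish embryos that carried a mutation named stac in the labels were compared with wild-type siblings at 24 and at 30 hours post fertilization (hpf), to find transcripts that were higher or lower in the mutant. The embryos came from crosses of heterozygous parents and were sorted by their appearance and by the fluorescence of a green reporter protein (EGFP), per the labels. The labels do not give the genotype of individual siblings, so the wild-type groups may hold heterozygous embryos. Each of the 4 groups (wild type at 24 hpf, mutant at 24 hpf, wild type at 30 hpf, mutant at 30 hpf) had 2 arrays described as biological repeats, 8 arrays in all, and this number limits the precision of every value. RNA was measured on an Affymetrix array with 15617 probe sets, of which 9301 with a signal above a set percentile were tested. No probe set was annotated to a stac gene (0 for stac, stac2 and stac3). The labels do not explain the name, so whether the mutated gene is on the array is not known, and the labels were not checked against it.

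Replicate arrays had Pearson correlations of 0.981 to 0.987 across probe sets, and arrays of the other genotype at the same age 0.976 to 0.989. At 30 hpf arrays correlated at 0.984 (wild type) and 0.986 (mutant) within groups and at 0.976 to 0.981 across genotypes. At 24 hpf the values overlapped: replicate 1 of the wild type was closer to mutant replicate 1 (0.989) than to its own replicate (0.981). The median SD between replicates was 0.10 to 0.12 on the log2 scale. The first principal component held 43.9% of the variance and separated the ages. The second held 15.9%, with the 30 hpf mutant arrays at 13.3 and 14.6 and the 30 hpf wild-type arrays at -13.6 and -10.7. On the next component, with 11.7%, replicate 2 of the 24 hpf wild type stood at -18.2 and replicate 1 at 8.01. The deposited arrays differed in scale: replicate 1 of the 30 hpf wild type had a trimmed mean signal of 500.1, and the other arrays lay between 58.9 and 80.8. All values below come after the arrays were brought to one scale.

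**Figure D1:**
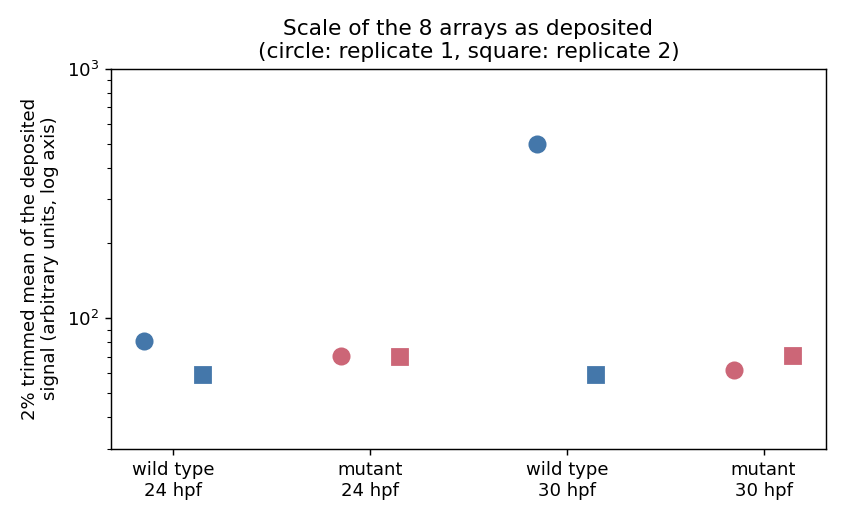
Trimmed mean of the deposited signal (vertical axis, arbitrary units, log scale) for each of the 8 arrays, by group, with replicate 1 as circles and replicate 2 as squares. Replicate 1 of the 30 hpf wild type sits at 500.1 and the other 7 arrays between 58.9 and 80.8.

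At 30 hpf, 8 of 23 genes of the Notch pathway and 11 of 38 proneural genes fell in the mutant and 0 of either rose. Both list calls were lost with a correlation estimated from the arrays (adjusted p = 0.146 with an estimated correlation for each). Transcripts of the Hairy-related repressors her4.2 (log2 fold change -1.80 ± 0.18, SE, adjusted p = 0.000644), her15.2 (-1.51 ± 0.13, adjusted p = 0.000221) and her2 (-1.89 ± 0.24, adjusted p = 0.00277), which act downstream of Notch receptors, fell. So did neurod4, a basic helix-loop-helix factor of neuronal differentiation (-1.57 ± 0.20, adjusted p = 0.0023), and atoh1a, a proneural factor of the hindbrain and of sensory hair cells (-1.23 ± 0.26, adjusted p = 0.044). On the other side, fsta, which encodes the activin-binding protein follistatin, rose by 1.79 ± 0.21 (adjusted p = 0.00168), and the p53-responsive gene phlda3 rose 2.47-fold (SE 0.26 on the log2 scale, adjusted p = 0.0291). A second probe set of fsta gave 0.96 ± 0.21 and did not pass (adjusted p = 0.051). In limma with Benjamini-Hochberg adjustment, 41 probe sets rose and 73 fell, 114 in all with 86 named genes among them. Of these probe sets, 6 rose and 28 fell by at least 2-fold. Calls without exactly 1 symbol numbered 22. Among probe sets with no symbol 4 rose and 14 fell. They include the largest rise of all calls (3.14 ± 0.62, adjusted p = 0.0282) and falls of -2.38 ± 0.31 and -2.26 ± 0.26.

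**Figure D2:**
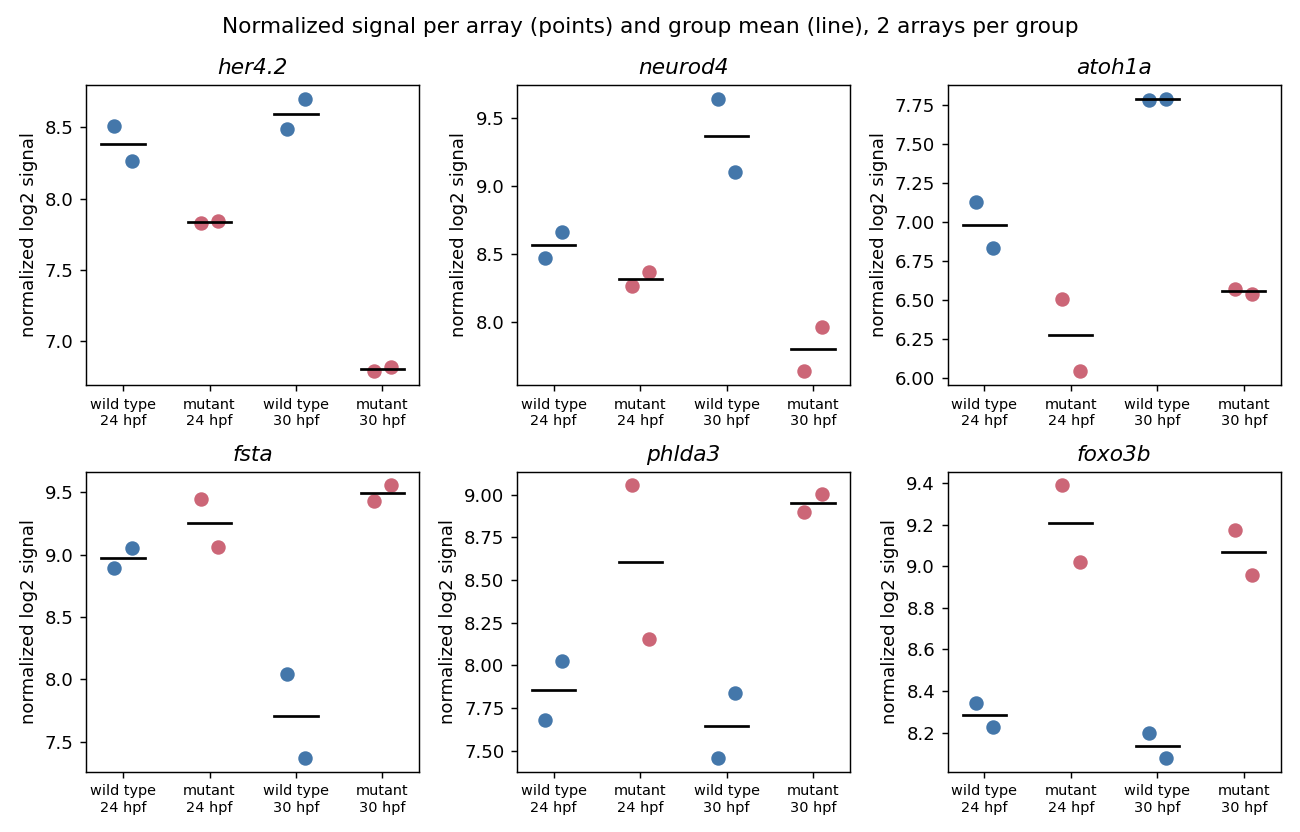
Normalized log2 signal (vertical axis) of 6 genes on each array, by group, with points for the 2 arrays and a line for their mean. At 30 hpf both mutant arrays lie below both wild-type arrays for her4.2, neurod4 and atoh1a, and above them for fsta, phlda3 and foxo3b.

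The proneural and neural progenitor list had 38 measured genes at 30 hpf. Of these, 11 fell and 0 rose over all genes tested, 23 fell when adjusted over the list alone, and the median was -0.40 (adjusted p = 1.8e-16 by camera with a preset correlation). With an estimated correlation the adjusted p was 0.146. Examples are the zinc-finger factor insm1b (-1.06 ± 0.12), ascl1b (-1.03 ± 0.14) and neurog1 (-1.09 ± 0.18), which are transcription factors of early neurons. In the Notch pathway and Hairy-related list, 8 of 23 genes fell and 0 rose, 9 fell when adjusted over the list alone, and the median was -0.41 (adjusted p = 2.93e-12, but 0.146 as the adjusted p with an estimated correlation). The fringe glycosyltransferase lfng was among those that fell (-0.63 ± 0.10). The probe sets of the her4 and her15 copies can bind RNA of near-identical tandem copies, so the value of each single copy is uncertain. Among genes of differentiated neurons, neurod1 fell (-0.91 ± 0.18), and 34 of 35 did not pass the test. Over the list alone 5 fell and 1 rose. The median of that list was -0.02 (adjusted p = 0.487).

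Ribosome biogenesis and nucleolar genes were higher in the mutant at 30 hpf. Of 92 genes, 9 rose and 0 fell, 26 rose when adjusted over the list alone, and the median was 0.29 (adjusted p = 1.8e-16 by camera with a preset correlation, adjusted p = 0.288 with an estimated correlation). The nucleolar factors wdr43 (0.61 ± 0.09), nop58 (0.51 ± 0.09), ddx18 (0.63 ± 0.11) and gnl3 (0.68 ± 0.12) rose. Heat shock and chaperone genes had a median of 0.07, with 1 of 38 past the test, dnajb1b (0.72 ± 0.13), and 2 when adjusted over the list alone (adjusted p = 0.0307 for the list, adjusted p = 0.582 with an estimated correlation). The chaperone list lost its call without wild type replicate 1 (median 0.02, adjusted p = 0.32), without mutant replicate 2 (median 0.05, adjusted p = 0.0869), with median centring (0.0529), with scaling alone (0.0635) and with the filter at the 60th percentile (0.0582). Its median was 0.11 without mutant replicate 1 and 0.14 with no filter, where the call was kept. Notochord and cartilage matrix genes had a median of 0.13, with 0 of 21 past the test over all genes and 0 when adjusted over the list alone (adjusted p = 0.039 for the list, adjusted p = 0.582 with an estimated correlation), and that call was lost without wild type replicate 1 (adjusted p = 0.149), without mutant replicate 1 (median 0.08, adjusted p = 0.611) and with the filter at the 60th percentile (0.119). The p53 list had a median of 0.11 at 30 hpf and did not pass (adjusted p = 0.2), with 4 of 26 up and 2 down, and 9 up and 2 down when adjusted over the list alone. In it rps27l (0.99 ± 0.16), foxo3b (0.93 ± 0.16) and phlda3 rose, and btg2, an antiproliferative gene, fell (-0.64 ± 0.10). Cell cycle genes were split, with 7 of 104 up and 2 down, and 12 up and 5 down when adjusted over the list alone (adjusted p = 0.803). The mitotic regulator cdc20 rose (0.70 ± 0.10), while the cyclin-dependent kinase inhibitor cdkn1ca fell (-0.85 ± 0.10). Skeletal muscle genes had a median of 0.04 and 0 of 38 passed the test.

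Other named genes that rose at 30 hpf were fosab, an AP-1 subunit (1.46 ± 0.28), etnk1 (0.99 ± 0.18), dnttip2 (0.89 ± 0.12), irf2bp1 (0.88 ± 0.15), pik3r3a (0.86 ± 0.17) and rhocb (0.84 ± 0.12). Those that fell were her4.5 (-2.48 ± 0.28), si:ch211-132d3.4 (-1.35 ± 0.19), the homeobox genes gbx1 (-1.22 ± 0.20) and dbx1a (-1.13 ± 0.18), and bhlhe22 (-1.14 ± 0.17). A second probe set of irf2bp1 gave 0.06 and other probe sets of rhocb gave -0.19 and 0.05, none past the threshold, so these 2 rises rest on 1 probe set each. The 30 hpf count fell from 114 to 18 without wild type replicate 1, to 33 without mutant replicate 1, to 48 without mutant replicate 2, and to 3 when limma's prior variance was not allowed to follow signal. On the values as deposited, where 1 array has another scale, it was 0. Of the 20 genes named by rule at 30 hpf, 6 passed without wild type replicate 1 and the same 6 without mutant replicate 1, namely fsta, her15.2, her2, her4.2, her4.5 and neurod4; the calls for atoh1a, phlda3, rps27l, foxo3b and the other 10 were lost in both. Without mutant replicate 2, 11 of the 20 passed. Without the trend in prior variance 2 passed, her15.2 and her4.2, so fsta, her2, her4.5 and neurod4 lost their calls there. With no filter on low values 17 passed, and atoh1a, fosab and phlda3 did not; atoh1a also did not pass without replicate 1 of the 24 hpf wild type.

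**Figure D3:**
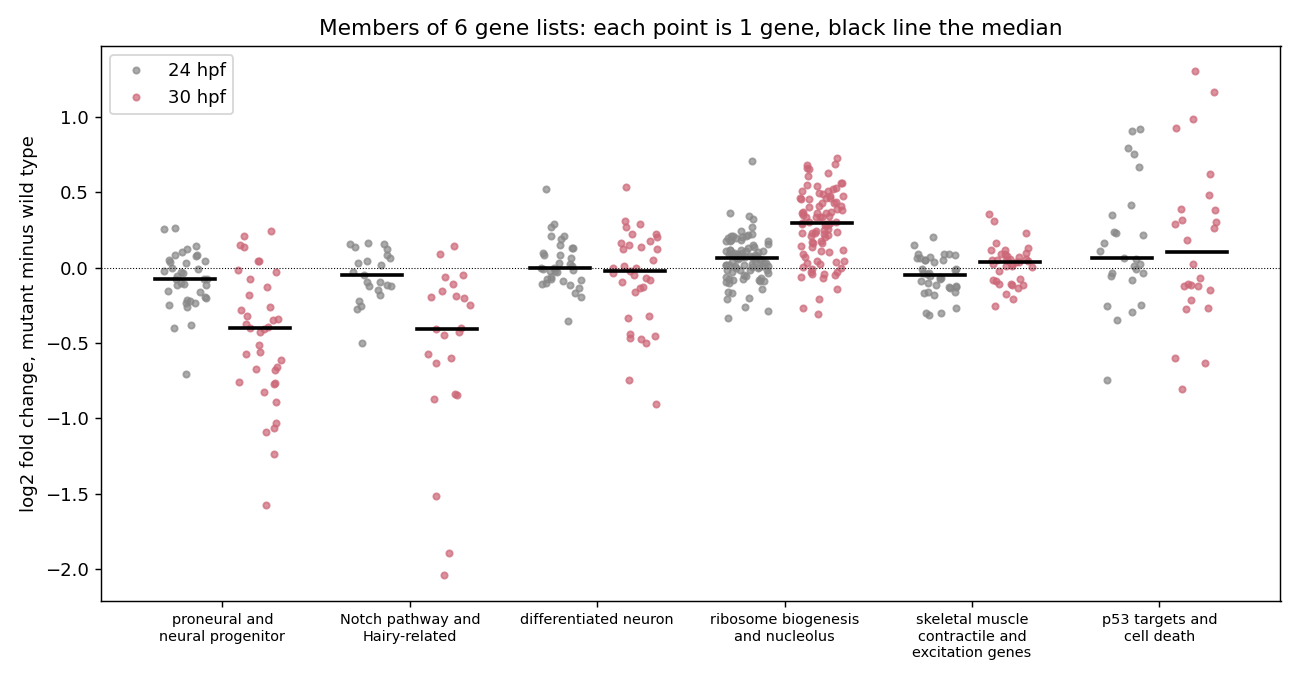
Log2 fold change of mutant minus wild type (vertical axis) for the members of 6 gene lists, each point 1 gene, grey at 24 hpf and red at 30 hpf, with black lines for the medians. The proneural median is -0.08 at 24 hpf and -0.40 at 30 hpf, and the ribosome biogenesis median 0.06 and 0.29; these medians were obtained after quantile normalization.

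At 24 hpf no gene passed the threshold between mutant and wild type, and the values with the smallest p are given without a call. The forkhead gene foxo3b had a log2 difference of 0.92 ± 0.16, fosab 2.03 ± 0.39 (0.81 and 0.94 for its other probe sets), ccdc34 1.40 ± 0.27, rps27l 0.67 ± 0.16 and gstt1a 0.49 ± 0.12. On the lower side were zgc:77262 (-0.58 ± 0.12, with -0.37 and -0.36 for its other probe sets), kdm5bb (-0.48 ± 0.11), meis2b (-0.63 ± 0.16), eef2l2 (-0.77 ± 0.22, with -0.22 for its other probe set) and tyms (-0.35 ± 0.10). The limma count was 0 with a smallest adjusted p of 0.613. An unadjusted p below 0.05 was reached by 267 probe sets, where 465 are expected with no effect. This shortfall was not explained, and 0 calls do not show that the genotypes were alike at 24 hpf. The number of adjusted calls remained small with any 1 array left out. Among 40 lists, p53 targets and cell death genes had a median of 0.06, with 0 of 26 past the test over all genes and 3 higher when adjusted over the list alone (adjusted p = 0.0131 for the list, adjusted p = 0.885 with an estimated correlation). The list was no longer past the threshold without mutant replicate 1 (adjusted p = 0.323), where its mean was 0.07 against 0.15 with all arrays and its median 0.08 against 0.06. That median was 0.17 without wild type replicate 1, 0.13 without mutant replicate 2, 0.03 with median centring and 0.14 with the filter at the 60th percentile. The number of lists past the threshold was 1 with all arrays, 5 without wild type replicate 2, 2 without wild type replicate 1 or mutant replicate 2, 5 with median centring and 4 with scaling alone.

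Averaged over both ages, the mutant had higher fosab (1.90 ± 0.27, adjusted p = 0.00759), foxo3b (0.93 ± 0.12, adjusted p = 0.00516) and rps27l (0.83 ± 0.11, adjusted p = 0.00699), and lower her4.2 (-1.17 ± 0.13, adjusted p = 0.00153), ascl1b (-0.71 ± 0.10, adjusted p = 0.00748) and insm1b (-0.64 ± 0.09, adjusted p = 0.00699). The other genes that rose were fsta (1.04 ± 0.15), phlda3 (1.03 ± 0.18), pik3r3a (0.73 ± 0.12), irf2bp1 (0.67 ± 0.11), rhocb (0.63 ± 0.08), dnttip2 (0.62 ± 0.09) and leo1 (0.52 ± 0.09). A second probe set of leo1 gave 0.00, one of irf2bp1 0.07, one of fsta 0.68 and one of fosab 1.08, and the other probe sets of rhocb gave -0.12 and 0.03. None of these passed. The other genes that fell were her4.5 (-1.60 ± 0.20), atoh1a (-0.97 ± 0.19), neurod4 (-0.91 ± 0.14), her15.2 (-0.89 ± 0.09), bhlhe22 (-0.72 ± 0.12), ptprna (-0.65 ± 0.12) and neurog1 (-0.64 ± 0.13). In all 17 probe sets rose and 33 fell, and 48 of these 50 were also past the threshold at 30 hpf alone. The proneural (median -0.25) and Notch (median -0.20) lists were lower and the ribosome biogenesis (median 0.16) and p53 (median 0.08) lists higher. With an estimated correlation their adjusted p were 0.159, 0.159, 0.319 and 0.703. Of the members, 5 proneural genes and 3 Notch genes fell, and 1 ribosome biogenesis gene, nop58 (0.36 ± 0.06), and 3 p53 genes rose. Adjusted over the list alone, 18 proneural and 8 Notch genes fell, 15 ribosome biogenesis genes rose, and in the p53 list 9 rose and 2 fell. The count of 50 was 1 without the trend in prior variance and 16 to 27 without replicate 1 of any group or replicate 2 of the 24 hpf wild type. Without replicate 2 of the 30 hpf mutant, or with median centring, 7 lists passed. The p53 list had a median of 0.04 and an adjusted p of 0.0508 without replicate 1 of the 30 hpf wild type, and a median of 0.13 without replicate 1 of the 24 hpf wild type and of 0.12 with the filter at the 60th percentile. Of the 20 genes named by rule, 10 to 17 passed with 1 array left out, 17 with no filter (all but atoh1a, neurog1 and phlda3) and 1 without the trend, her4.2.

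Whether the genotype difference itself changed between the ages was tested as an interaction. No single gene passed, and the values with the smallest p were her15.2 (-1.24 ± 0.18, adjusted p = 0.0655), cdkn1ca (-0.85 ± 0.14), lfng (-0.76 ± 0.14), btg2 (-0.69 ± 0.13) and si:ch211-132d3.4 (-1.79 ± 0.36) on the lower side at 30 hpf. On the higher side were fsta (1.51 ± 0.29), cdc20 (0.70 ± 0.14), the nucleolar factor wdr43 (0.61 ± 0.13), mcm3 (0.59 ± 0.13) and nol10 (1.02 ± 0.23). A second probe set of fsta had genotype differences of 0.40 at 24 hpf and 0.96 at 30 hpf, against 0.28 and 1.79 for the one named. A second probe set of mcm3 had a 30 hpf difference of 0.13 that did not pass, against 0.44 for the one named. The count in limma was 0, with 658 probe sets at an unadjusted p below 0.05 where 465 are expected with no effect. It was 3 under scaling alone, and 1, 4 and 6 without replicate 1 of the 30 hpf wild type, replicate 2 of the 30 hpf mutant and replicate 1 of the 24 hpf wild type. As lists, proneural (median -0.35) and Notch (median -0.36) genes had a lower and ribosome biogenesis genes (median 0.25) a higher genotype effect at 30 than at 24 hpf by camera with a preset correlation. The ribosome biogenesis median was 0.14 without replicate 1 of the 30 hpf wild type. With an estimated correlation the adjusted p were 0.293, 0.244 and 0.527. Adjusted over the list alone, 12 proneural, 8 Notch and 3 ribosome biogenesis genes passed. The number of lists was 3 with all arrays and 5 without replicate 2 of the 24 hpf wild type or any 1 of replicate 2 of the 30 hpf wild type and both 30 hpf mutant arrays, with median centring and with scaling alone.

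From 24 to 30 hpf, in the mean of both genotypes, 28 of 38 skeletal muscle genes rose and 45 of 92 ribosome biogenesis genes fell. The list calls for age were all lost with an estimated correlation (smallest adjusted p = 0.0842). The calcium-binding parvalbumin pvalb1 rose by 3.14 ± 0.08 (adjusted p = 2.42e-10), fast troponin T tnnt3b by 2.77 ± 0.10, and the lens crystallins crybb1 and cryba4 by 2.67 ± 0.18 and 2.62 ± 0.18. The vitamin B12 carrier gene tcnbb rose by 4.47 ± 0.28 and the mitochondrial carrier slc25a4 by 3.31 ± 0.16. Genes that fell were cyp11a1.1, which encodes a steroid-forming enzyme (-3.04 ± 0.21), the presomitic mesoderm factor msgn1 (-2.84 ± 0.24), uox (-2.46 ± 0.17), the muscle regulator myog (-2.12 ± 0.15), jam2a (-1.67 ± 0.20) and wu:fi42e03 (-1.65 ± 0.21). In the skeletal muscle list 28 of 38 rose and 2 fell (median 0.63, adjusted p = 9.82e-30, adjusted p = 0.19 with an estimated correlation), 30 and 2 when adjusted over the list alone. In the ribosome biogenesis list 45 of 92 fell and 0 rose, among them npm1a and ubtf (median -0.33, adjusted p = 1.6e-16, adjusted p = 0.215 with an estimated correlation), 61 when adjusted over the list alone. Differentiated neuron genes were higher (median 0.48, 21 of 35 rose, 25 over the list alone, adjusted p = 6.67e-13, adjusted p = 0.19 with an estimated correlation), among them cplx2a (0.79 ± 0.09) and dpysl3 (0.98 ± 0.11). Glycolysis and hypoxia genes were higher too (median 0.36, 19 rose and 2 fell of 35, the same counts when adjusted over the list alone, adjusted p = 1.02e-08, adjusted p = 0.0842 with an estimated correlation), with pgam2 at 1.25 ± 0.07. Myogenic regulators were lower (median -0.61, -0.35 with no filter, 4 of 7 fell, 6 over the list alone, adjusted p = 9.73e-05, adjusted p = 0.505 with an estimated correlation). Splicing genes were lower (median -0.15, 22 of 108 fell and 1 rose, 25 and 1 over the list alone, adjusted p = 2.41e-05), as were ribosomal protein genes (median -0.04, adjusted p = 0.00574, a median of 0.00 with scaling alone and a median of -0.06 with an adjusted p of 0.398 with median centring). Segmentation and tailbud genes had a median of -0.27 (adjusted p = 0.0315, 0.167 with a median of -0.16 without replicate 2 of the 24 hpf wild type and 0.0736 with median centring). With the filter at the 60th percentile that median was -0.03 (adjusted p = 0.597). Higher lists were primitive erythroid (median 0.12, 0.17 without replicate 1 of the 30 hpf wild type and 0.20 with scaling alone), collagen and other matrix (median 0.18, 0.12 with median centring), oxidative phosphorylation (median 0.07, adjusted p = 0.232 and a median of 0.01 with median centring), yolk syncytial layer (median 0.10, 0.15 without replicate 2 of the 24 hpf wild type, adjusted p = 0.0789 without replicate 1 of the 24 hpf wild type) and the unfolded protein response (median 0.15, 0.07 with median centring, adjusted p = 0.0639 without replicate 2 of the 24 hpf mutant and 0.092 with the filter at the 60th percentile). With an estimated correlation the adjusted p was 0.505 for splicing, ribosomal protein, segmentation, erythroid and yolk genes, 0.549 for collagen and for oxidative phosphorylation and 0.258 for the unfolded protein response. In the order fell, then rose, adjusted over the list alone, 1 and 0 ribosomal protein genes passed, 2 and 0 segmentation, 5 and 11 erythroid, 5 and 10 collagen, 0 and 1 oxidative phosphorylation, 5 and 15 yolk and 6 and 10 unfolded protein response genes. In all 13 of 40 lists passed with a preset correlation and 0 with an estimated one.

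The age comparison called 1332 probe sets, 661 up and 671 down. With median centring in place of quantile normalization the split was 537 up and 1033 down. Within wild type 414 rose and 353 fell, and with median centring 303 rose and 546 fell. Within mutants 300 rose and 243 fell. The wild-type count of 767 was 255 without 30 hpf replicate 1 and 263 without 24 hpf replicate 2. The mutant count of 543 was 213 and 194 without the 24 hpf replicates and 166 and 339 without the 30 hpf replicates, and without the trend in prior variance the wild-type and mutant counts were 305 and 178. In the mean of both genotypes the count was 850 without replicate 2 of the 24 hpf mutant, 800 without replicate 1 of the 30 hpf mutant and 862 without the trend.

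Across 6271 genes, the mean genotype effect and the mean age effect, which come from orthogonal contrasts of the 8 arrays, had a Pearson r of -0.02 and a Spearman rho of -0.02. Of the 1332 probe sets called for age, 695 had a genotype effect of the opposite sign, 52.2%. The genotype effects at 24 and at 30 hpf, which share no arrays, had a Pearson r of 0.13 and a Spearman rho of 0.08. Genes are not independent replicates, so no p is given. Of the 114 probe sets called at 30 hpf, such as her4.2 and fsta, 88 had the same sign at 24 hpf: 32 of the 41 that rose and 56 of the 73 that fell. Their median effect at 24 hpf was 0.12 for the first set and -0.12 for the second. The Pearson r between ages was 0.0224 without replicate 1 and 0.214 without replicate 2 of the 24 hpf wild type. That of genotype with age was 0.139 without replicate 1 of the 24 hpf wild type, -0.189 without replicate 2 of the 30 hpf wild type and 0.141 without replicate 2 of the 30 hpf mutant; contrasts with an array missing are no longer orthogonal.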

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

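The list tests on the difference between ages and on age, and the tests of neural tissue, the rescaled array, whole-embryo delay and the mutant array below, were chosen after the results were seen. The other tests are recorded as written beforehand. Those of them on single gene lists still address patterns that these data had shown, so they are not independent of the results.

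The genotype effect of 3 gene lists differed between 24 and 30 hpf by the test of the difference itself. The median difference, 30 minus 24 hpf, was -0.35 for proneural genes (adjusted p = 5.88e-11) and -0.36 for Notch and Hairy-related genes (adjusted p = 2.45e-10), and 0.25 for ribosome biogenesis genes (adjusted p = 1.32e-09). With an estimated correlation the adjusted p were 0.293, 0.244 and 0.527. The ribosome biogenesis median was 0.14 without replicate 1 of the 30 hpf wild type.

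Lower proneural and Notch genes at 30 hpf could be a delay in development. In wild type these lists had median age effects of 0.14 and 0.29, but the 30 hpf mutant lay below even the 24 hpf wild type, by medians of -0.26 and -0.10. The leave-one-out SDs were 0.0225 and 0.026. These SDs show how far leaving out 1 array moves a median, also for arrays outside this contrast, and are not standard errors. Both medians lay below 0 by more than these SDs, where a delay would put them at or above 0. The values argue against a delay of the proneural genes. They also argue against a delay of the Notch genes as a list, with a smaller margin. A loss of neural tissue as a whole is argued against by the differentiated neuron list, with a median of -0.0185 beside -0.403 (over that list alone 5 fell and 1 rose), and the array of another scale by a proneural median of -0.32 without it. Binding among her copies does not account for the Notch list, whose median was -0.40 over the 17 members that are not her genes. A change in neural progenitors of the mutant remains a hypothesis, and a lower share of those cells in whole embryos stays open.

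Higher ribosome biogenesis genes at 30 hpf were set beside their fall with age. The 30 hpf mutant lay between the wild-type ages on this list (median -0.15 against the 24 hpf wild type, where wild type itself fell to -0.43), which is consistent with a delay of these genes. The genotype rise and the wild-type fall with age share the 30 hpf wild-type arrays with opposite signs. An error in those arrays alone can place the mutant between the ages, so this position cannot decide about a delay. A delay of the whole embryo of the same extent would put the skeletal muscle list at -0.39, a value that rests on the same differences. That list stood at 0.0404 with a leave-one-out SD of 0.0427. The median without the array of another scale was 0.21.

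Whether higher p53 target genes at 24 hpf rest on mutant replicate 1 stays open: without it the list's adjusted p was 0.323 and its mean went from 0.15 to 0.07, but its median went from 0.06 to 0.08. In the mean of both ages the adjusted p was 0.0373 without that array, so that call does not need it. That call was lost without replicate 1 of the 30 hpf wild type (adjusted p = 0.0508, median 0.04) and with an estimated correlation (adjusted p = 0.703). Handling stress cannot be told apart from genotype here: in the mean of both ages the immediate early list had a median of 0.0082 and a test direction of down (adjusted p = 0.833), over members that moved both ways, such as fosab up and dusp1 down at 30 hpf.

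Other splits of the 8 arrays into 4 and 4, with age kept in the fit, were run for the mean genotype effect. Of 34 splits that could be fitted, the real one included, 2 gave at least as many genes as the real 50. The highest other count was 68. The split with 68 kept the 30 hpf genotypes apart and mixed those at 24 hpf. Nearly all other splits mix the genotypes of an age within a group, which puts the genotype difference into the spread. The share of splits, which is not under 0.05, therefore cannot decide about chance, and chance is not excluded for that count. For gene lists, 24 of 34 splits gave at least the real 4, with up to 9, so chance is not excluded for the number of lists. The proneural median was larger in the real split than in each of the others, with 1 of 34 as large, against 2 for Notch, 3 for ribosome biogenesis and 8 for p53. These are the 4 lists that passed in this comparison on the same arrays. That favours a high rank of the real split, so the ranks are no independent support. For age, 1 of 34 splits gave as many genes as the real 1332, the highest other being 0. Nearly all other splits mix 24 and 30 hpf arrays within a group, which puts the age difference into the spread. Counts of 0 were therefore likely beforehand, and this comparison cannot exclude chance. For age lists, 2 of 34 gave at least 13, the highest other being 13, so chance is not excluded for the number of lists.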

How the results depend on the processing

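The values as deposited were the main setting fixed beforehand. Their replacement by quantile normalization as the main setting was decided after the data were seen. So were scaling without quantile normalization and the list tests on the difference between ages and on age. Where an array is left out, the lone array of its group is assumed to vary like the other groups. The cause was not tested except where stated.

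The 139 results for named genes had the same direction in every alternative that gave them a value, apart from the values as deposited. At the 60th percentile filter 123 of the 139 had a value, and 138 in each fit without a 24 hpf array. In the alternatives that gave a value, apart from left-out arrays and the values as deposited, 58 stayed on the same side of the threshold. Without the trend in prior variance, 58 named results no longer passed; at a pseudocount of 32 all 139 stayed on their side.

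With 1 array left out, the counts of genes ranged from 0 to 2 at 24 hpf, 18 to 125 at 30 hpf, 16 to 54 in the mean of both ages, 0 to 6 for the difference between ages, 255 to 669 for age in wild type, 166 to 588 in mutants and 800 to 1278 in the mean of both genotypes. Counts of lists ranged from 0 to 5 at 24 hpf, 5 to 6 at 30 hpf, 4 to 7 in the mean of both ages, 3 to 5 for the difference between ages and 12 to 14 for age. The correlation of genotype with age effects ranged from -0.189 to 0.141, and that between the genotype effects at both ages from 0.0224 to 0.214; the latter was 0.0484 with no filter.

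Without the trend in prior variance, 3 genes passed at 30 hpf, 1 in the mean of both ages, 305 for age in wild type, 178 in mutants and 862 in the mean. At an adjusted p below 0.1 the counts were 211 at 30 hpf, 83 in the mean of both ages, 3 for the difference between ages and 837 for age in mutants, with 5 lists for the difference between ages; the looser threshold itself gives these. With only the 4 arrays compared, 503 genes passed for age in wild type against 767, and 640 in mutants against 543. With an estimated correlation 0 lists passed at 24 hpf, 30 hpf, in the mean of both ages, for the difference between ages and for age.

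With a replicate block nested in age, 2 genes passed at 24 hpf, 278 at 30 hpf, 137 in the mean of both ages, 34 for the difference between ages, 1242 for age in wild type and 951 in mutants. With a replicate block across all arrays, 82 passed in the mean of both ages and 4 for the difference between ages. Deviations from the group mean correlated at 0.133 between wild type and mutant of 1 number at 24 hpf and at 0.198 at 30 hpf, against 0.0041 to 0.0627 for the other pairs of groups. The labels do not say that a number marks a shared clutch, so blocked values stand only here.

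With median centring, 5 lists passed at 24 hpf, 7 in the mean of both ages and 5 for the difference between ages. With scaling alone, 3 genes passed for the difference between ages, and 4 lists at 24 hpf and 5 for the difference between ages; the ribosomal protein median with age became 0.0014. With the filter at the 60th percentile, 3 lists passed at 30 hpf.

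On the values as deposited, the array on the larger scale moved the median of all probe sets by -1.35 at 30 hpf, -0.66 in the mean of both ages, -1.40 for the difference between ages and 0.61 for age in the mean of both genotypes, which is why directions reversed. Then 0 genes passed at 30 hpf, 0 in the mean of both ages, 2 for age in wild type, 0 in mutants and 3 in the mean. List medians became, at 30 hpf, -1.30 for heat shock, -1.23 for notochord and -1.06 for ribosome biogenesis. They became -0.59 for p53 and -0.50 for ribosome biogenesis in the mean of both ages, and -1.15 for ribosome biogenesis in the difference between ages. With age they became 0.61 for ribosomal protein, 0.28 for ribosome biogenesis, 0.41 for segmentation and 0.47 for splicing.

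Genes that reversed on the values as deposited were, at 30 hpf, phlda3 (-0.095), etnk1 (-0.40), rps27l (-0.38), foxo3b (-0.46), dnttip2 (-0.48), irf2bp1 (-0.51), pik3r3a (-0.51), rhocb (-0.52), cdc20 (-0.65), ccnb1 (-0.86), dnajb1b (-0.65), hspd1 (-0.95), hspa4a (-0.91), hspe1 (-1.17), col2a1a (-1.06), ccn2a (-1.09), lamc1 (-0.83), cnmd (-1.07), wdr43 (-0.76), nop58 (-0.87), ddx18 (-0.73) and gnl3 (-0.69). In the mean of both ages they were irf2bp1 (-0.0038), rhocb (-0.055), dnttip2 (-0.045), leo1 (-0.14), nop58 (-0.33), wdr43 (-0.38), nop2 (-0.28) and dkc1 (-0.32). For the difference between ages they were cdc20 (-0.68), wdr43 (-0.75), mcm3 (-0.77), nol10 (-0.39), ddx18 (-0.73) and gnl3 (-0.73), and for age rpl7l1 (0.19), rpl10a (0.56), npm1a (0.16) and snrpd1 (0.28).

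Signal over background limits dim probe sets, and those under the filter were not tested.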

Other observations

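Of 35 immediate early genes, 1 rose and 3 fell in the mutant at 30 hpf. The transcription factor subunit fosab rose (1.78 ± 0.39 for 1 of its 3 probe sets), while btg2 (-0.64 ± 0.10), ier5 (-0.54 ± 0.10) and the phosphatase gene dusp1 (-0.53 ± 0.11) fell, and 31 of 35 members did not pass. Over the list alone 1 rose and 4 fell, and the list was not past the threshold by camera (adjusted p = 0.612). Another probe set of fosab did not pass at 30 hpf (1.22 ± 0.40, adjusted p = 0.193).

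Of 104 cell cycle genes at 30 hpf, 7 rose, 2 fell and 95 did not pass. Besides cdc20 and cdkn1ca, the mitotic cyclin gene ccnb1 rose (0.52 ± 0.09) and the ribonucleotide reductase gene rrm2l fell (-0.46 ± 0.07). In the cell cycle list the median was -0.03 and the direction of the test was up, with an adjusted p of 0.803.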
